A study of Mus musculus with 8 samples.

How the data were processed

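RNA from bone-marrow-derived macrophages of WT and Dnmt3a KO mice was sequenced as 8 libraries, 4 per genotype. Per the labels' protocols, marrow cells were grown with 30 ng/ml M-CSF and 10% serum, were taken at day 8 to 10, and 10 ng of RNA entered each poly(A) library. The kit does not mark strand, so reads of antisense and overlapping genes cannot be told apart. Trimmomatic 0.39, STAR 2.7.0a and featureCounts were used with genome build mm10, per the submitters' processing notes. The settings and annotation of the counting are not given in the sources used here.

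The values used are raw read counts per gene symbol, as the authors deposited them, for 26667 genes. The authors also deposited a table of their own comparison, which gives a mean of normalised counts, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value per gene. The deposited header of that table carries the column names of a DESeq2 result, and the tool is not named in the sources used here. That table was used only to count shared calls. In 25 rows the gene symbol had turned into a date, and these held 0.215% of the counts and were left under those names. Library totals ran from 12614006 to 28502631 counts.

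Genes were kept with edgeR 4.0.16 (filterByExpr, minimum count 10), which left 12507. They were scaled by TMM and tested with the edgeR quasi-likelihood test on genotype in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change is its size over the square root of the F statistic. The smallest exact permutation p for 4 against 4 libraries is 0.0286. Of 853 symbols in the gene lists and the fixed genes, 830 were found in the table, 18 of them through RefSeq synonyms of GRCm38.p6, which is the mm10 assembly and gave the positions. A list was tested when at least 5 of its genes were tested, by camera in limma 3.58.1 with a preset correlation of 0.01. Camera with an estimated correlation, fry, and an exact permutation test of per-library list scores were run beside it. A score is the mean over list members of log2 CPM (prior count 2) less the gene's mean over the 8 libraries. By fry, 11 of 30 lists passed after adjustment. By the exact permutation test 13 lists reached the smallest p and 0 passed after adjustment, against 23 by camera with the preset correlation. At its smallest p a list passes that adjustment only if most of the 30 lists reach it, so 0 passing says little. The lists share some genes, so their results are not independent.

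The gene lists, the fixed genes, the tests of the comparison and all alternatives but 2 were set before the data were examined, while some tests of explanations were chosen after the results were seen. The text names the fixed genes whatever their result. It also names the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM and all 4 libraries of one genotype above all 4 of the other. Predicted genes and immunoglobulin and T-cell receptor segments were passed over. In each list it names up to 3 called members with the smallest adjusted p. Some genes that the rule takes are not reported here.

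The alternatives were RLE, upper-quartile or no scaling factors, no filter (at least 1 count in all), a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, a replicate block, each library left out, a log2 fold change of at least 1, and camera with an estimated correlation. Removal of each library's trend on transcript length and GC content (loess, span 0.3) was added after the data were seen, as was the removal of Dnmt3a from the list of DNA methylation. Lengths and GC came from the longest GENCODE transcript per gene, and 97.5% of tested genes had one.

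The gene tests, camera, the exact permutation test of list scores and the trend removal were tested on simulated counts. These were drawn for the 12507 genes from the means and sizes of these libraries, with the spread estimated without genotype. For the gene tests, changes were planted in genes with a mean of at least 1 CPM. The search for runs of neighbouring called genes was tested on randomly placed calls. The other tests, fry among them, were not simulated. For the comparison of Dnmt3a KO with WT, edgeR recovered 8% of 50 genes changed by a log2 fold change of 0.5, 66% at 1, 98% at 2 and 80% at -1. Of its 135 calls 6.67% were false, against 19.6% with DESeq2 and 10% with limma-voom, and it made 0 calls with no change planted. DESeq2 and limma-voom were run on 1 draw alone. Genes were drawn independently of each other, so these rates need not hold for the calls in the real libraries. Over 10 further draws edgeR recovered 8% to 22% at 0.5, 68% to 84% at 1, 96% to 100% at 2 and 58% to 82% at -1, with 2.27% to 9.29% of its calls false, so the values of the first draw are rough. Fold changes of genes with few counts are imprecise, and changes near 0.5 log2 units would mostly be missed at this depth and number of libraries.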

Results

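Poly(A) RNA was sequenced from bone-marrow-derived macrophages, cells grown from mouse marrow in the presence of the growth factor M-CSF, of 2 genotypes. There were 4 libraries from wild-type (WT) cultures and 4 from cultures lacking Dnmt3a, an enzyme that places new methyl groups on DNA, all taken at day 8 to 10 of differentiation. The counts assigned to genes came to 16213187, 15505309, 16496001 and 28502631 in WT replicates 1 to 4. In Dnmt3a KO replicates 1 to 4 they came to 13341515, 20801015, 12614006 and 17809015. Nothing in the labels says whether the 4 libraries of a genotype came from separate mice, so the p-values measure the spread between these libraries. WT libraries carry the library numbers 1 to 4 and KO libraries 9 to 12, so any effect of library order cannot be separated from genotype. The comparison asks which transcripts differ between resting macrophages with and without Dnmt3a.

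Dnmt3a itself separated the genotypes in every library. Its level was 150, 155, 168 and 170 CPM (read counts scaled to a common library size) in WT replicates 1 to 4, and 29.1, 37.6, 35.6 and 35.4 CPM in KO replicates 1 to 4. The mean fell from 161 ± 10.0 CPM (SD, n = 4) to 34.4 ± 3.70 CPM (SD, n = 4), a log2 fold change of -2.22 ± 0.11 (SE) with an edgeR quasi-likelihood adjusted p of 1.08e-06. The KO libraries still held 2233 counts on the gene, against 12538 in WT. A gene-level count does not show which exons these counts cover. The gene lies on chromosome 12 from 3801559 to 3914443 in mm10.

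Of 12507 genes tested, 152 were higher and 49 lower in Dnmt3a KO macrophages, 201 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them, 100 rose and 18 fell by at least 1 log2 unit. All 4 libraries of one genotype lay above all 4 of the other for 200 of the 201 genes. Over all tested genes 9.41% were separated in this way, where chance gives 2.86%. Leaving out WT replicate 1, which stood apart from the rest, raised the count to 484, while the count was 103 without WT replicate 2 and 120, 126 and 118 without KO replicates 1, 2 and 4. The count of lower genes was also smaller without WT replicate 3 (29) and KO replicate 3 (25). The count of all called genes was 399 with no filter on low counts and 511 with DESeq2. Of the 55 called genes that the text may name, 31 kept their call in all 17 alternatives run on single genes. The other 24 lost it in at least 1. The threshold of 1 log2 unit is not among these 17.

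The largest fall among the genes named by the fixed rule was in Ctse, which encodes the aspartic protease cathepsin E. Ctse dropped from 67.5 ± 6.32 to 3.12 ± 0.60 CPM (SD, n = 4 each), a log2 fold change of -4.45 ± 0.17 (SE; edgeR adjusted p 1.51e-07). It lies on chromosome 1 from 131638314 to 131675507. Steap3, an endosomal ferrireductase on chromosome 1, fell from 99.1 ± 5.38 to 32.8 ± 3.73 CPM, 3.02-fold. Ptprv, annotated as a transcribed pseudogene, fell 4.08-fold, and it overlaps the neighbouring gene Ptpn7, so reads in the overlap cannot be assigned with certainty. Nid2, which encodes the basement membrane protein nidogen, fell 2.60-fold. Zfp651, H1fx, Zfhx2 and Cuedc1 were also among the 10 strongest falls, with log2 fold changes of -1.75, -1.64, -1.31 and -1.28. The calls of Zfp651, H1fx and Zfhx2 were lost in 6, 6 and 5 of 17 alternatives, each without WT replicate 2 and without any of KO replicates 1 to 3, among others, with edgeR adjusted p up to 0.126, 0.151 and 0.0912 when single libraries were left out. With limma-voom the calls of Zfp651 and Zfhx2 were lost as well. In H1fx and Cuedc1 the highest WT value was that of replicate 1, at 16.8 and 36.2 CPM.

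The largest rise was in C2, the gene of complement component 2, on chromosome 17 from 34862602 to 34882100. C2 was at 0.26 ± 0.18 CPM in WT, with 18 counts over the 4 libraries, and at 27.2 ± 4.78 CPM in KO, with 1793 counts (log2 fold change 6.80 ± 0.31, SE; edgeR adjusted p 8.10e-07). Lta, which encodes the cytokine lymphotoxin alpha, lies on chromosome 17 from 35203165 to 35205578. It went from 0.22 ± 0.15 to 3.54 ± 0.71 CPM, with a log2 fold change of 4.02 ± 0.41. Cd4, a T-cell coreceptor that some macrophages also carry, rose from 1.11 ± 0.83 to 13.3 ± 7.04 CPM. Fabp7, a fatty acid binding protein gene, rose from 6.00 ± 1.65 to 37.9 ± 9.12 CPM, 6.26-fold. Il23a, a subunit gene of the cytokine interleukin-23, rose 7.52-fold and Il17rc, a subunit gene of an interleukin-17 receptor, 7.10-fold. Serpinh1, which encodes a collagen chaperone, rose 11.8-fold from 0.39 to 4.51 CPM. Atp6v0e2, Ptpn14 and Mxra8 rose from 8, 7 and 11 counts over the WT libraries to 284, 149 and 148 over the KO libraries, so their log2 fold changes of 5.31 ± 0.49, 4.54 ± 0.62 and 3.93 ± 0.60 rest on few WT counts.

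**Figure D1:**
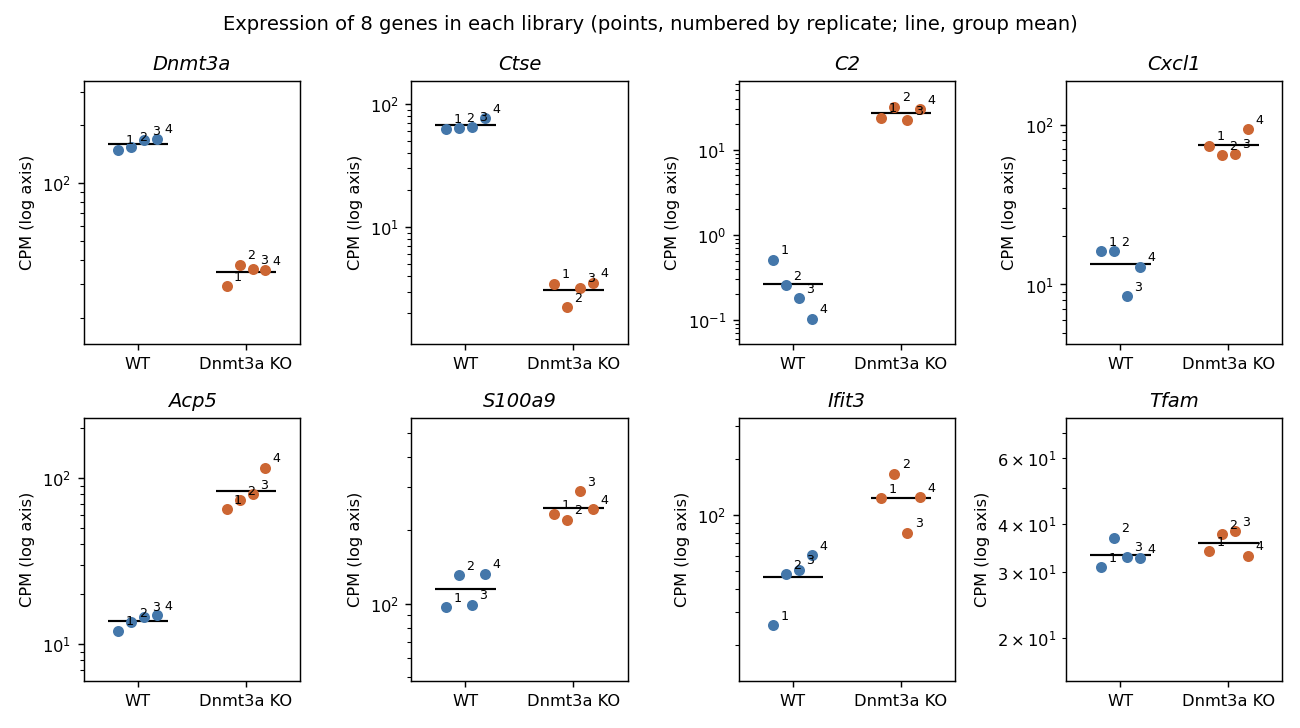
Level of 8 genes in CPM on a log axis, with 1 point per library numbered by replicate and a line at each group mean (n = 4). Dnmt3a and Ctse lie lower in all 4 Dnmt3a KO libraries, C2, Cxcl1, Acp5, S100a9 and Ifit3 lie higher in all 4, and Tfam overlaps between the genotypes.

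The list of inflammatory genes was higher as a whole in the KO cultures. Of 40 tested members of the list of inflammatory cytokines and NF-kB targets, 9 rose, 0 fell and 31 did not pass the test. Adjusted over the list alone, 24 rose. The neutrophil-attracting chemokine gene Cxcl1 went from 13.4 ± 3.65 to 74.4 ± 13.5 CPM (SD, n = 4 each), a log2 fold change of 2.47 ± 0.21 (SE; edgeR adjusted p 1.32e-04). Cxcl2 rose 2.21-fold, from 93.4 ± 18.2 to 206 ± 21.7 CPM. Tnf was at 96.9 ± 10.5 CPM in WT and 136 ± 10.8 CPM in KO, with an edgeR adjusted p of 0.0517. Il1b was at 17.6 and 31.2 CPM with an edgeR adjusted p of 0.0709, and Il6 was below the filter in both genotypes, with 12 and 13 counts. Tnf and Il1b were called with no filter on low counts, with DESeq2, without WT replicate 1 and with the length and GC trend removed, and Tnf also with RLE scaling. The mean log2 fold change of the list was 0.68 (camera adjusted p 2.56e-24, and 0.0246 with an estimated correlation). Its per-library score was higher in all 4 KO libraries than in any WT library (two-sided exact permutation p 0.0286, the smallest that 70 arrangements allow, and 0.0659 after adjustment over 30 lists).

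The score of genes induced by type I interferon was higher in most but not all KO libraries. Of 59 tested members, 8 rose and 0 fell, while 58 had a positive log2 fold change. With p adjusted over the list alone, 46 rose. Ifit3, an antiviral effector gene, went from 46.0 ± 14.7 to 123 ± 35.3 CPM, 2.67-fold, with an edgeR adjusted p of 0.0181. Its near-identical neighbour Ifit3b, listed under an older symbol, rose 2.63-fold, and reads shared between the 2 copies make both values uncertain. Oasl1 rose 2.45-fold. Isg15, which encodes a ubiquitin-like protein, rose 2.04-fold, from 50.1 ± 5.37 to 102 ± 30.2 CPM. The chemokine gene Cxcl10 rose 1.89-fold and Irf7, a transcription factor gene of the interferon response, 1.83-fold. Of these, the calls of Ifit3, Oasl1, Isg15, Cxcl10 and Irf7 were lost when single libraries were left out. All 5 were lost without WT replicate 2 and also without KO replicate 1. Over all single libraries left out, their edgeR adjusted p reached 0.0680, 0.0580, 0.112, 0.120 and 0.156. With limma-voom the calls of Isg15 and Irf7 were lost, and without scaling factors that of Irf7. Ifnb1, the interferon beta gene, had 7 counts over the WT and 12 over the KO libraries and was not tested.

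The mean log2 fold change of the type I interferon list was 0.76 (camera adjusted p 4.33e-32). The list's call was lost at adjusted p = 0.152 with an estimated correlation. Its score was -1.06, -0.33, -0.17 and -0.02 in WT replicates 1 to 4 and 0.44, 0.70, -0.07 and 0.53 in KO replicates 1 to 4. KO replicate 3 thus lay below WT replicate 4, and the two-sided exact permutation p was 0.0571. In the list of interferon gamma response genes, 5 of 25 rose and 0 fell, among them Igtp (2.02-fold), Cd274, the gene of the checkpoint ligand PD-L1 (2.06-fold), and Gbp3 (2.29-fold). The calls of Cd274 and Gbp3 were lost without WT replicate 3, KO replicate 1 or KO replicate 2, and that of Gbp3 also without WT replicate 2 or KO replicate 4, with edgeR adjusted p up to 0.0776 and 0.0936. When p was adjusted over the list alone, 14 rose. Its mean log2 fold change was 0.71, with a camera adjusted p of 4.91e-14 and an adjusted p = 0.0523 with an estimated correlation.

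Among genes that sense nucleic acids, 1 of 25 tested genes rose, Irf7, and 0 fell. Adjusted over the list alone, 3 rose and 1 fell. Cgas, which encodes the sensor of cytosolic DNA and is listed under an older symbol, was at 39.2 ± 6.25 CPM in WT and 43.4 ± 2.98 CPM in KO. Tmem173, which encodes its adaptor STING, was at 37.3 ± 4.07 and 33.9 ± 3.71 CPM. Neither passed the edgeR test, with adjusted p of 0.690 and 0.698. The list's mean log2 fold change was 0.21, with a camera adjusted p of 0.00662 that became 0.255 with an estimated correlation.

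The list of neutrophil-lineage genes was higher as a whole in the KO cultures. Of 17 tested members of the list of neutrophil and granulocyte precursor markers, 6 rose and 0 fell, and all 17 had a positive log2 fold change. With p adjusted over the list alone, 14 rose. S100a9 and S100a8, whose products form the calprotectin complex, went from 115 ± 19.7 to 247 ± 29.8 CPM and from 65.5 ± 16.4 to 145 ± 20.2 CPM. Mmp8, the neutrophil collagenase gene, rose 2.43-fold, from 60.3 ± 20.3 to 147 ± 18.4 CPM. The list's mean log2 fold change was 0.84 (camera adjusted p 5.26e-21, and 0.0246 with an estimated correlation). Its score was higher in all 4 KO libraries than in any WT library.

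The list of genes of osteoclasts, the bone-resorbing cells that share a precursor with macrophages, was also higher as a whole. Of 11 tested members, 4 rose and 0 fell. When p was adjusted over the list alone, 6 rose. Acp5, which encodes tartrate-resistant acid phosphatase, went from 13.8 ± 1.31 to 83.2 ± 22.1 CPM, a log2 fold change of 2.59 ± 0.18 (SE; edgeR adjusted p 2.29e-05). Dcstamp, needed for cell fusion, rose 1.64-fold, and the integrin gene Itgb3 2.07-fold. Both calls were lost without WT replicate 2, KO replicate 2 or KO replicate 4, and that of Dcstamp also without KO replicate 1, with edgeR adjusted p up to 0.0709 for Dcstamp and 0.0700 for Itgb3. The mean log2 fold change was 0.70 (camera adjusted p 1.09e-09, and 0.0246 with an estimated correlation).

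In the list of cholesterol efflux and lipid handling, 2 of 31 tested genes rose and 0 fell. These were the scavenger receptor gene Marco, from 3.17 ± 0.75 to 13.4 ± 3.16 CPM (4.21-fold), and Fabp5, a fatty acid binding protein gene, from 14.1 to 27.5 CPM. The call of Fabp5 was lost without WT replicate 2 or any of KO replicates 2 to 4, with edgeR adjusted p up to 0.0930. Adjusted over the list alone, 5 rose. Over the list, the mean log2 fold change was 0.30 (camera adjusted p 2.52e-05, and 0.0246 with an estimated correlation). In the lysosome list 3 of 35 rose, with Ctsh, the cathepsin H gene, at 152 ± 6.34 CPM in WT and 232 ± 13.7 CPM in KO. The others were Atp6v0d2, a proton pump subunit gene (2.77-fold), and Gpnmb (1.73-fold). The call of Gpnmb was lost in 10 of 17 alternatives, with upper-quartile or no scaling, the stricter filter and limma-voom and on leaving out any single library but WT replicate 1 and KO replicate 4, with edgeR adjusted p up to 0.152. That of Atp6v0d2 was lost without scaling factors and without WT replicate 2, WT replicate 4 or any of KO replicates 2 to 4, with edgeR adjusted p up to 0.144. With p adjusted over the list alone, 3 lysosome genes rose. The lysosome list had a mean log2 fold change of 0.16 and a camera adjusted p of 0.00662, which became 0.348 with an estimated correlation and 0.0618 without WT replicate 3.

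None of 23 tested members of the macrophage list passed the edgeR test over all genes, and adjusted over the list alone 2 rose. Csf1r, the M-CSF receptor gene, was at 2109 ± 99.5 CPM in WT and 2063 ± 243 CPM in KO, with a 95% interval of the log2 fold change from -0.29 to 0.22. Emr1 (Adgre1, a surface marker gene of mature macrophages) was at 506 ± 56.6 and 565 ± 54.7 CPM. The lysozyme gene Lyz2 was at 5619 ± 540 and 7698 ± 1145 CPM, with an edgeR adjusted p of 0.112, and was called with DESeq2, without WT replicate 1 and with the length and GC trend removed. The macrophage list had a mean log2 fold change of 0.16, a camera adjusted p of 0.0147 and an adjusted p = 0.269 with an estimated correlation. Its score was higher in all 4 KO libraries than in any WT library, but without KO replicate 4 the mean log2 fold change was 0.095 and the camera adjusted p 0.183. Of the alternative activation list, 2 of 19 rose, the chitinase-like gene Chi3l3 (2.22-fold) and the glucan receptor gene Clec7a (2.25-fold). The call of Clec7a was lost without WT replicate 2, WT replicate 4 or any of KO replicates 2 to 4, with edgeR adjusted p up to 0.110. When p was adjusted over the list alone, 6 rose and 1 fell. Arg1 was at 1.36 ± 0.48 and 1.76 ± 0.59 CPM, and Mrc1 at 207 ± 107 and 206 ± 31.1 CPM, with 69.7 CPM in WT replicate 1.

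Markers of other blood and stromal cell types were also tested. In the monocyte list 2 of 15 rose, Chi3l3 and the haptoglobin gene Hp (1.76-fold), and 3 did so adjusted over the list alone. In the erythroid and megakaryocyte list 2 of 10 rose and 1 fell. Itga2b rose 2.30-fold to 27.7 ± 4.28 CPM and Gp1bb 2.81-fold to 2.96 CPM, while Vwf, the von Willebrand factor gene, dropped from 80.6 ± 11.2 to 53.4 ± 4.56 CPM. The calls of Hp, Gp1bb and Vwf were lost in 6, 8 and 7 of 17 alternatives, most of them single libraries left out, where the edgeR adjusted p reached 0.0954, 0.164 and 0.118, and the others upper-quartile scaling for Gp1bb and the removed length and GC trend for Vwf. Adjusted over the list alone, 5 rose and 1 fell. In the B-cell list 1 of 5 tested genes rose, Cd22, from 1.11 to 3.49 CPM, and in the T and NK cell list 1 of 5, Cd4. The counts adjusted over the list alone were also 1 in each. Neither the dendritic cell list (19 genes), the mast cell, basophil and eosinophil list (8 genes), the stromal and endothelial list (6 genes) nor the stem and progenitor list (14 genes) had a member that passed over all genes. With p adjusted over the list alone, 1 gene rose and 1 fell in the mast cell list and in the stem and progenitor list, and 0 passed in the other 2.

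The mean log2 fold changes of these lists were 0.31 for monocytes, 0.72 for erythroid cells and megakaryocytes, 0.49 for B cells, 1.12 for T and NK cells and 0.15 for dendritic cells. They were 0.50 for mast cells, 0.43 for stromal cells and 0.14 for stem cells. The T and NK cell mean rests largely on Cd4 (3.52), the median of that list being 0.50, and the erythroid mean was 0.34 with no filter on low counts. Camera called the monocyte, erythroid, B-cell, T and NK cell, mast cell and stromal lists with the preset correlation, at adjusted p of 0.00153, 6.40e-05, 0.0321, 5.27e-04, 0.0435 and 0.0415. With an estimated correlation their adjusted p = 0.255, 0.0609, 0.152, 0.0521, 0.269 and 0.291. The B-cell call was also lost without WT replicate 1, WT replicate 3 or KO replicate 3, the mast cell call without WT replicate 1 or 2 or KO replicate 3 or 4, and the stromal call without WT replicate 1 or 2 or KO replicate 4, with camera adjusted p up to 0.0684, 0.164 and 0.130. The B-cell call was lost with limma-voom, with the replicate block and with no filter on low counts, where the mean was 0.30. The mast cell call was lost with the stricter filter, and the stromal call with the stricter filter and DESeq2. The dendritic cell and stem cell lists had camera adjusted p of 0.215 and 0.342, and the dendritic cell list was called without KO replicate 2. With single libraries left out the means of the dendritic, stromal and stem cell lists ran from 0.079 to 0.27, 0.28 to 0.58 and -0.051 to 0.14.

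Among the enzymes and partners of DNA methylation, 2 of 19 tested genes fell, Dnmt3a and Tet3, and 0 rose, with the same counts adjusted over the list alone. Tet3, which encodes an enzyme that oxidises methylcytosine, went from 212 ± 21.0 to 155 ± 2.45 CPM, with an edgeR adjusted p of 0.0442. That call was lost without scaling factors and with the replicate block. It was also lost on leaving out any single library but WT replicate 1, with edgeR adjusted p up to 0.150. Dnmt1, the maintenance methyltransferase gene, was at 153 ± 11.7 and 130 ± 8.01 CPM (edgeR adjusted p 0.322). Its cofactor Uhrf1 was at 58.4 and 46.9 CPM, Dnmt3b at 7.53 and 7.86 CPM, Dnmt3l at 7.95 and 10.5 CPM, and Tet2 at 96.6 and 83.6 CPM, with none past the threshold. The list's mean log2 fold change was -0.18, with a camera adjusted p of 0.00126 and an adjusted p = 0.113 with an estimated correlation. That list holds the targeted gene, and without Dnmt3a the mean of the other 18 genes was -0.063, with a camera adjusted p of 0.276, so the rest of the list was not called. In the imprinted list, Cdkn1c, a cell cycle inhibitor gene, rose from 25.4 ± 3.60 to 68.0 ± 6.69 CPM (edgeR adjusted p 1.93e-04), and the noncoding transcript Peg13 dropped from 15.2 ± 1.35 to 9.69 ± 1.27 CPM. The call of Peg13 was lost with limma-voom and with the replicate block. The Peg13 call was also lost on leaving out any single library but WT replicate 1, with edgeR adjusted p up to 0.146. The other 16 of 18 tested did not pass, and adjusted over the list alone 2 rose and 2 fell. The mean log2 fold change was 0.25 (camera adjusted p 0.0409, and 0.152 with an estimated correlation). That call was lost with the stricter filter, DESeq2, limma-voom and the replicate block. It was also lost without WT replicate 3 or 4 or KO replicate 1 or 2, at camera adjusted p up to 0.157. With no filter on low counts the mean of the imprinted list was 0.69. Of 32 germline genes known to be silenced by methylation, 2 had enough counts to be tested, and neither passed.

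Tfam, which encodes the packaging and transcription factor of mitochondrial DNA, was at 33.3 ± 2.56 CPM in WT and 35.7 ± 2.62 CPM in KO, with a log2 fold change of 0.10 and a 95% interval from -0.16 to 0.37. None of the 33 tested genes of mitochondrial DNA maintenance and transcription passed, over all genes or adjusted over the list alone, and the list's camera adjusted p was 0.932. Of 76 nuclear-encoded genes of oxidative phosphorylation, 0 passed by either adjustment. That list's mean log2 fold change was -0.13 (camera adjusted p 0.0335, and 0.684 with an estimated correlation), and 0.03 without WT replicate 1, and the call was lost without KO replicate 3. Transcripts encoded by the mitochondrial genome were not analysed here.

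In the cell cycle list, 2 of 42 tested genes had a positive log2 fold change, the others a negative one, and 0 passed singly, over all genes or adjusted over the list alone. The mean was -0.19 (camera adjusted p 2.53e-05, and 0.160 with an estimated correlation). Its score was lower in all 4 KO libraries than in any WT library (two-sided exact permutation p 0.0286, adjusted 0.0659). In the Nrf2 target list Gclm, a subunit gene of the enzyme that starts glutathione synthesis, rose 1.40-fold. In the glycolysis and hypoxia list Pfkfb3, a regulator of glycolytic flux, rose 1.39-fold, and in the list of MHC class II presentation and costimulation the receptor gene Cd40 rose 1.55-fold. Each was the 1 gene of its list that passed, by either adjustment, out of 25, 29 and 16 tested. The call of Gclm was lost without scaling factors, with the replicate block and with the length and GC trend removed. The Gclm call was also lost on leaving out any single library but WT replicate 1 and KO replicate 2, with edgeR adjusted p up to 0.126. That of Pfkfb3 was lost without scaling factors and on leaving out any single library but WT replicate 1, and that of Cd40 on leaving out any of WT replicates 2 to 4, KO replicate 1 or KO replicate 4, with edgeR adjusted p up to 0.144 and 0.0833. Cd74, the invariant chain gene of MHC class II, was at 1092 ± 208 and 1361 ± 302 CPM.

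Camera called the Nrf2, MHC class II, alternative activation and cholesterol synthesis lists higher, at adjusted p of 3.71e-04, 0.00688, 0.00601 and 0.0105 and mean log2 fold changes of 0.17, 0.23, 0.28 and 0.19. With an estimated correlation their adjusted p = 0.269, 0.255, 0.291 and 0.431. With no filter on low counts the mean of the alternative activation list was 0.65. With single libraries left out it ran from 0.18 to 0.37, and that of the cholesterol synthesis list from 0.11 to 0.26. The MHC class II call was also lost without WT replicate 2 (camera adjusted p 0.0541), and the cholesterol synthesis call without WT replicate 2 or KO replicate 4 (up to 0.126). The lists of glycolysis, MHC class I presentation, p53 targets and the unfolded protein response were not called, with mean log2 fold changes of -0.04, 0.04, 0.16 and 0.08. With single libraries left out these means ran from -0.10 to 0.047, -0.029 to 0.10, 0.034 to 0.22 and 0.017 to 0.13. The MHC class I list was called without WT replicate 1 or KO replicate 3, the p53 list without WT replicate 2 or KO replicate 4, both with the length and GC trend removed, and the unfolded protein list without WT replicate 1 or KO replicate 4. In the cholesterol synthesis, MHC class I, p53 and unfolded protein lists 0 genes passed over all genes. When p was adjusted over the list alone, 1 unfolded protein response gene rose. Of the 30 lists tested, 23 were called with the preset correlation, 20 higher and 3 lower, of which the DNA methylation list was lower through Dnmt3a itself. The 4 inflammatory, neutrophil, osteoclast and lipid handling lists were also called with an estimated correlation.

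**Figure D2:**
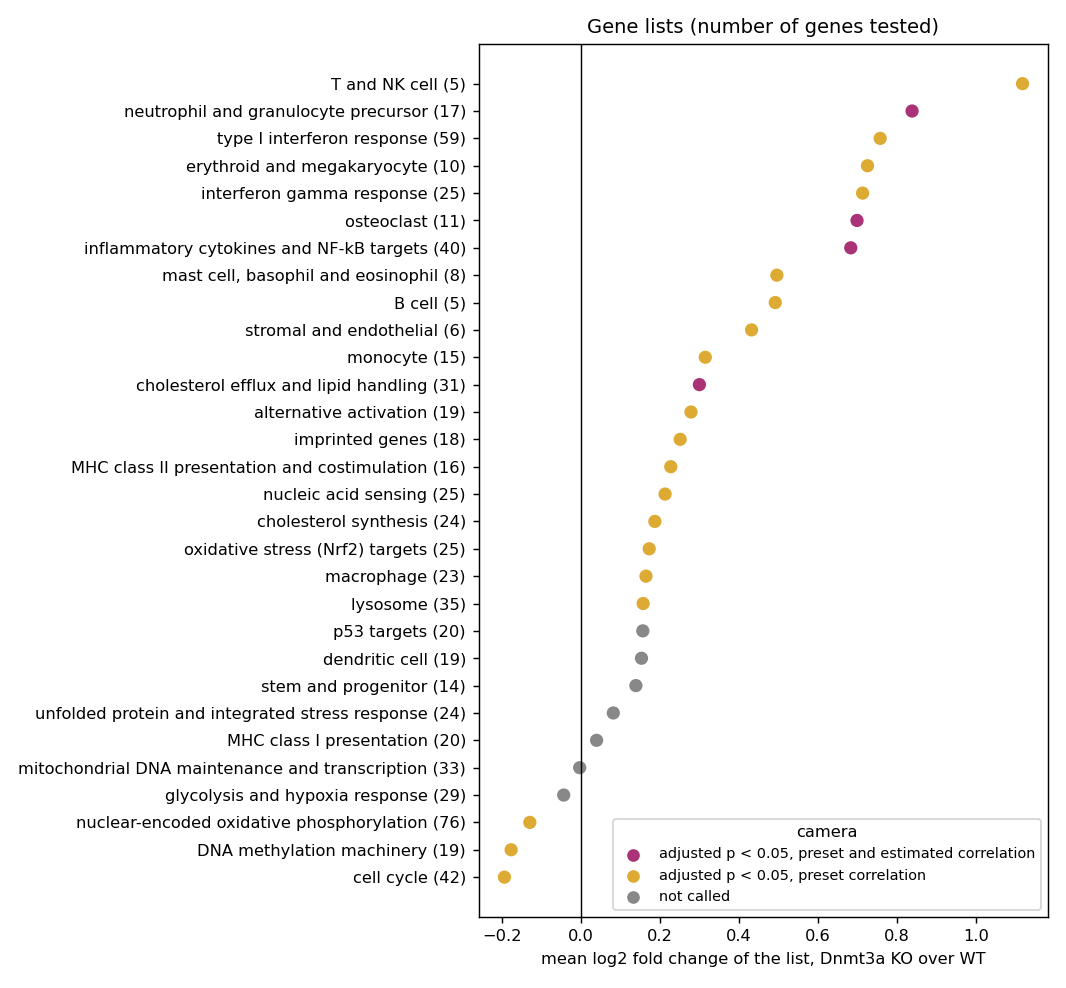
Mean log2 fold change, Dnmt3a KO over WT, of the 30 gene lists tested, with the number of tested genes in brackets. The 4 lists also called with an estimated correlation are those of neutrophils (0.84), osteoclasts (0.70), inflammatory genes (0.68) and lipid handling (0.30).

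WT replicate 1 stood apart from the other libraries. Its median correlation of log2 CPM with the other WT libraries, across genes, was 0.962, against 0.986 to 0.990 for every other library within its genotype. It had 15225 genes with a count, where the other WT libraries had 16621 to 16799, and 2.28% of its counts lay on the ribosomal RNA gene Rn45s, against 0.459% to 1.19% elsewhere. It also had the lowest scores of the 8 libraries for the type I interferon, interferon gamma, inflammatory, neutrophil, osteoclast and lipid handling lists. Without it the mean log2 fold changes of the type I interferon, inflammatory and neutrophil lists were 0.60, 0.64 and 0.76, and all 3 were still called with the preset correlation, though with an estimated correlation and all libraries the type I interferon list was not (camera adjusted p 0.152).

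**Figure D3:**
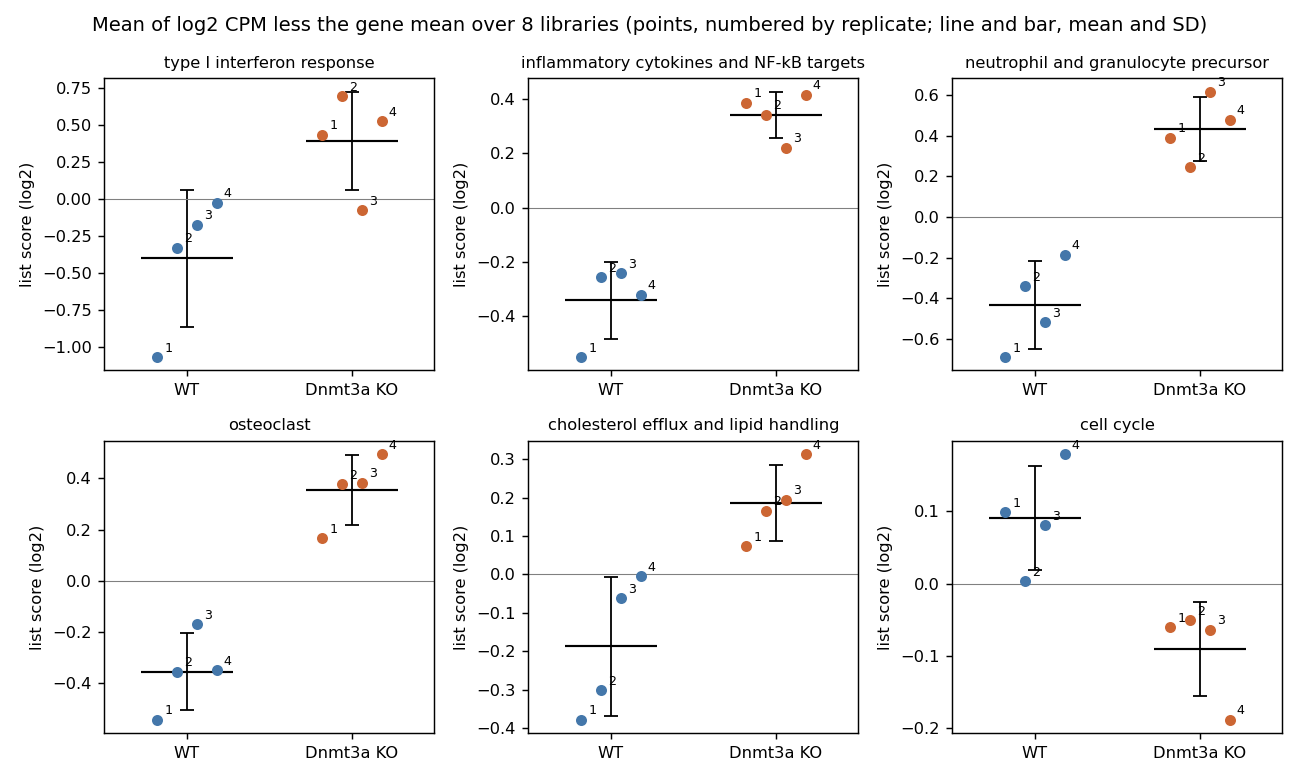
Score of 6 gene lists in each library, the mean over tested members of log2 CPM less the gene's mean over 8 libraries, with points numbered by replicate and bars for the mean and SD (n = 4). WT replicate 1 has the lowest type I interferon score (-1.06), and KO replicate 3 (-0.07) is the lone KO library below a WT library in that panel.

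The authors' deposited table of the same comparison lists 16108 genes, of which 507 have an adjusted p under 0.05. Dnmt3a has a positive log2 fold change in the authors' deposited table, so its fold changes were read as WT over KO, and in the other direction 344 of these genes were higher and 163 lower in KO. All 152 genes called higher and all 49 called lower with edgeR were also called, in the same direction, in the authors' deposited table. A further 306 genes were called in the authors' deposited table alone, 14 of them below the count filter used for edgeR.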

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

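The tests of WT replicate 1, of the cell types and of chromosome 1 were chosen after the results were seen, and the test of length and GC content before its result was seen. Of 214 groups of 4 libraries examined, 13 held a library far from the other 3, and chance alone gives about 5% of groups. In WT replicate 1, H1fx was at 16.8 CPM (the others 7.88 to 9.30), Cuedc1 at 36.2 CPM (22.1 to 23.6) and Vwf at 97.3 CPM (73.7 to 76.2), and it had 15225 genes with a count (16621 to 16799). WT replicate 4 had 28502631 counts in all (15505309 to 16496001). Isg15 was at 57.0 CPM in KO replicate 3 (115 to 120). In KO replicate 4, Ctsh was at 252 CPM (223 to 227), Mmp8 at 174 CPM (136 to 140), the cell cycle score was -0.19 (-0.06 to -0.05) and the macrophage score 0.27 (0.02 to 0.03). In KO replicate 2 the Nrf2 target score was -0.021 (0.12 to 0.14) and the dendritic cell score -0.23 (0.15 to 0.19). The mast cell, basophil and eosinophil score was 0.47 in KO replicate 3 (0.15 to 0.20).

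The real split of the 8 libraries gave 201 called genes, 152 in the commoner and 49 in the less common direction, where the highest of the other splits gave 1, 1 and 0. In each case 1 of the 35 splits, the real one, gave as many, which is the smallest share that 35 splits allow. Chance is thus made unlikely but is not excluded. Library order follows genotype, so the splits cannot tell those 2 apart. For the 4 lists called with an estimated correlation the real split was likewise the only one to give as many (highest other 1). By the exact permutation test 0 lists passed after adjustment, but a list could pass only if most lists reached the smallest p. For the 23 lists called with the preset correlation, 1 of the 35 splits gave as many but the highest other split gave 21, so that count says little by itself and points to a structure of the samples that the preset correlation does not take up.

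Interferon-stimulated genes were higher on average in the KO libraries, with a difference of mean scores of 0.79 ± 0.28 (SE; two-sided exact permutation p 0.0571). KO replicate 3 (-0.07) lay below WT replicate 4 (-0.02). The call of the type I interferon list was lost with an estimated correlation (camera adjusted p 0.152). Across genes, which are not independent replicates, the deviation of WT replicate 1 followed GC content (rho 0.67) and transcript length (rho -0.37). Each deviation was taken from the other libraries of the same genotype. Other libraries also had GC trends, with rho -0.35, -0.49 and -0.57 in WT replicates 2 to 4. In KO replicates 1 to 4 that rho was 0.37, -0.60, 0.11 and 0.25. With each library's trend removed the difference was 0.75 ± 0.26 (SE, two-sided exact permutation p 0.0571). That argues against these trends as the whole cause. The genotypes still overlapped, with the lowest KO score at -0.080 and the highest WT score at -0.047. Without WT replicate 1 it was 0.57 ± 0.19 (SE; two-sided exact permutation p 0.0857, smallest possible 0.0286), which argues against that library as the sole source. A response to the genotype and a difference between cultures that follows library order may both account for it, and neither was tested.

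Granulocyte genes were higher in the KO libraries, with a mean log2 fold change of 0.84 over 17 genes. Markers of the other cell types, 78 genes, had a mean of 0.41, a difference of -0.43 ± 0.10 (SE across genes, which are not independent replicates) from the granulocyte genes, and -0.45 ± 0.10 (SE across libraries) by per-library scores (two-sided exact permutation p 0.0286, the smallest possible). The test took a lower share of macrophages to raise all these markers alike. That holds only for markers that macrophages do not carry, which was not tested, so the difference does not decide it. The lists of T and NK cells (1.12) and erythroid cells (0.72) did not lie below the granulocyte genes by more than 2 SE. Those of dendritic cells (0.15), stem cells (0.14), monocytes (0.31), stromal cells (0.43), B cells (0.49) and mast cells (0.50) did. B cells and mast cells were near that limit, at differences of -0.38 ± 0.17 and -0.36 ± 0.17 (SE across libraries). The osteoclast list (0.70) was not among these markers. The macrophage list itself had a mean of 0.16. More neutrophil-lineage cells may be a source, which the test took to raise all members by 1 shared factor. That too holds only for members that macrophages do not carry, which was not tested. Of 17 members, 3 (Mmp8, Mmp9 and Csf3r) lay farther from the weighted mean of 0.85 than the limit of the test. That limit is narrower than the 95% interval, and 1 member (Csf3r) left the mean out of its 95% interval. The test was set to take at most 2 such members as going with a shared factor and at least 4 as going against it, and the count depends on the limit used, so more such cells and a change within macrophages cannot be told apart for these genes.

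On chromosome 1, 26 of 720 tested genes were called (3.61%), a higher share than on the other chromosomes (two-sided Fisher exact p 1.79e-04). That chromosome was picked because it holds the densest run of calls, which are among the 26. The p is not adjusted over chromosomes, so it adds no separate evidence to the run below. The densest run of 25 neighbouring tested genes held 8 calls, where 95% of 10000 random placements held at most 5 (p 2.00e-04). These were Ppfia4 and Rnpep, higher, and Ptprv, Ptpn7, Ipo9, Nav1, Kif21b and Ddx59, lower, genes chosen after their values were seen. Ptprv and Ptpn7 overlap, so their calls may not be independent. The run spans 134182156 to 136456192. Ctse, Steap3 and Marco lie before it on chromosome 1, starting at 131638314, 120226414 and 120474538. Whether the cause of the cluster also bears on them was not tested. A segment from another strain carried along with the knockout could give calls in both directions. Both directions also occur over all genes (152 higher, 49 lower), so they do not single out such a segment. In this region 2 calls were higher and 6 lower, another balance than elsewhere (two-sided Fisher exact p 0.00284). The genotype of that region was not analysed here and an effect of Dnmt3a on the region was not tested. Dnmt3a lies on chromosome 12, so a count in its flank decides nothing about this cluster, and the 0 of 37 tested genes called within 10 Mb of it (0%, against 1.62% elsewhere, one-sided Fisher exact p 1) are too few to judge a flanking segment.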

How the results depend on the processing

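Only the removal of the length and GC trend, and of Dnmt3a from the DNA methylation list, were chosen after the data were seen. No called gene reversed in any alternative, and the scaling alternatives moved the median of all genes by at most -0.015, without scaling factors. The count of 201 genes (152 higher, 49 lower) became 399 (302, 97) with no filter on low counts, 511 (347, 164) with DESeq2, 510 (381, 129) with the length and GC trend removed, and 118 (100, 18) with a log2 fold change of at least 1. Leaving out single libraries gave 103 to 484 genes (82 to 341 higher, 21 to 143 lower), with all 201 kept without WT replicate 1. The 23 called lists became 4 with an estimated correlation, 18 with the stricter filter, which left the B-cell and the T and NK cell lists untested, 21 with DESeq2 and with limma-voom, 22 with no filter, 25 with the length and GC trend removed, and 20 to 23 with single libraries left out. With an estimated correlation the lists of type I interferon (0.76), interferon gamma (0.71), cell cycle (-0.19) and erythroid genes (0.72) lost their calls; the mean does not depend on this setting. The DNA methylation list went from -0.18 to -0.063 with Dnmt3a taken out and was then not called (camera adjusted p 0.276). The oxidative phosphorylation list (-0.13) ran from -0.20 to 0.028 with single libraries left out, and reversed to 0.028 without WT replicate 1 (camera adjusted p 0.270); the cause was not tested. Of 55 called named genes, 32 to 55 were called with single libraries left out. Whether the replicate numbers pair the libraries cannot be told. Same-numbered deviations correlated across genes at 0.25, 0.28, 0.07 and -0.02. Of the 4 WT libraries 2, replicates 1 and 2, correlated best with their own number. The monocyte and cholesterol synthesis scores were lower in replicates 1 and 2 than in replicates 3 and 4 in both genotypes, while the type I interferon score was not. With the replicate block 260 genes were called, 178 of them shared, and Gclm, Peg13 and Tet3 and the B-cell and imprinted lists were not called, while Il1b was. Genes with few counts, such as Ifnb1 and Il6, lie below what this depth can compare.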

Other observations

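The genes here were chosen after their values were seen, so they describe these libraries and were not tested as groups. Genes of eicosanoid synthesis, the making of lipid mediators from arachidonic acid, were among the calls. Ptges, a prostaglandin E synthase gene, rose from 58.7 ± 3.98 to 212 ± 80.4 CPM (SD, n = 4 each; edgeR adjusted p 0.00156). Ptgs2, the inducible cyclooxygenase gene, rose to 57.0 ± 5.56 CPM, with a log2 fold change of 1.19, and Alox12, a lipoxygenase gene, from 1.44 to 5.93 CPM. Alox5, Ptgs1, Alox15 and Ltc4s did not pass, with log2 fold changes of 0.57, 0.63, -0.21 and 0.05. Genes of coagulation and complement were also called. F10, the factor X gene, rose from 10.4 ± 1.61 to 31.4 ± 5.31 CPM, F5 from 2.68 to 8.94 CPM, the thrombin receptor gene F2r from 3.33 to 12.1 CPM and Cfb, the complement factor B gene, from 3.58 to 10.0 CPM. C3, F7, F13a1 and C1qa did not pass, with log2 fold changes of 0.22, 0.64, 0.25 and 0.01.

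The homeobox gene Hoxb4 fell from 9.13 ± 1.59 to 4.70 ± 0.91 CPM (SD, n = 4 each; edgeR adjusted p 0.0340). Dppa3, a gene of germ cells and early embryos, rose from 0.86 ± 0.34 to 4.95 ± 1.66 CPM.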
